A study of Homo sapiens with 10 samples.

How the data were processed

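The series measured guide RNA abundance in a pooled CRISPR/Cas9 knockout screen in DND-41 cells. It holds 10 libraries: 1 from time zero and 3 each from DMSO, CB-103 and DAPT cultures at day 21. The submitters' labels give the treatment and replicate number of each library and say that guides were amplified from genomic DNA by nested PCR. They do not say whether the replicates of a treatment were separate cultures from the start of treatment.

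The authors deposited a table of raw read counts per guide for 119461 guides, which are whole numbers with library totals that differ. They also deposited a normalized table, used here as a signal on an arbitrary scale. In that table each value is the raw count of the same guide multiplied by 1 factor per library. The factors ran from 0.617 to 1.60 and brought the library medians to between 111 and 113. The programs bcl2fastq 2.19, FastQC 0.11.5 and MAGeCK 0.5.9.2 are named in the submitters' processing notes without their roles. How reads were matched to guides, and how many mismatches were allowed, is not given in the sources used here. All columns of both tables could be assigned to a library by name. No molecular identifiers were described, so PCR copies count as reads.

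Guide names divide the library into half-libraries, A with 63950 guides and B with 55511. The table pairs guides with 20707 gene entries, of which 1795 are microRNA entries, and with 1000 non-targeting control guides. Of the gene entries tested, 18534 matched a current or earlier symbol in a RefSeq gene table of GRCh38.p14, and 1328 of them carry another symbol there. Gene names are printed as in the deposited table. Guide sequences and genome positions were not used here. An entry with 9 guides bears a calendar date in place of a gene symbol. It was not interpreted, is not among these gene entries and was not tested as a gene.

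Guides with a mean count under 10 over the 10 libraries were left out, which removed 955 and kept 118506. The raw counts of the 9 endpoint libraries were scaled by the trimmed mean of M values and fitted together with the quasi-likelihood model of edgeR 4.0.16 in R 4.3.3, with robust dispersion and no covariates. The common dispersion was 0.296. Each contrast ranked all guides by their one-sided p. For each gene with at least 3 tested guides the ranks were combined by alpha-robust rank aggregation with alpha = 0.05, using the exact null distribution of the order statistics, separately for each direction. The p-values of the 20392 genes tested were adjusted by the Benjamini-Hochberg method within contrast and direction, and genes under 0.05 were called. This value is named the rank-aggregation adjusted p. Of the genes tested, 17374 had 6 tested guides, and 313 entries had too few guides.

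The size of a gene's effect is the mean over its guides of the difference in log2(normalized count + 1), with its standard error from limma 3.58.1. This average runs over active and inactive guides together, so it can be near 0 for a gene called through a few guides. Gene lists were tested with camera in limma, with a preset inter-gene correlation of 0.01, two-sided, and adjusted over 32 lists in 3 contrasts, 96 tests. The test was repeated with an estimated correlation and with fry. Fry asks whether the genes of a list moved one way on balance and does not compare them with other genes. The lists, fixed before the data were examined, cover Notch, PI3K and cytokine signalling, the G1 phase, apoptosis, leukaemia transcription factors and chromatin genes, general essential complexes, mitochondrial complexes and olfactory receptors as a non-essential control. Members are also counted as adjusted over the list alone.

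Changes from time zero use a single starting library, so no p-value was computed for the changes themselves. They are means over guides of the endpoint minus time zero log2(normalized count + 1), with the SD over 3 endpoint libraries. A list's median change was placed among 10000 random lists of the same size matched on mean abundance. The per-library median change from time zero of 179 genes from 5 essential lists was compared between groups by an exact two-sided permutation test, for which 3 libraries against 3 cannot give a p below 0.10.

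The genes to be named were chosen by a rule written before the data were examined. It takes the 12 genes with the smallest p in each direction for each inhibitor against DMSO and the 6 in each direction for the direct comparison. It also takes the 8 genes with the lowest and the 8 with the highest change from time zero in DMSO, among those with at least 4 tested guides. A fixed set of Notch, PI3K, G1 and leukaemia genes was always included. List members past 0.05 adjusted over the list alone, and up to 4 members with the smallest p of each list that passed, complete the rule. A few of the genes it selects are not reported here.

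Library totals ran from 10016567 to 27980083 counts, so 3 counts correspond to 0.107 to 0.300 CPM. Replicate libraries differed by more than counting noise, with chi-square per degree of freedom from 12.4 to 53.9 between pairs of a group, so all were kept as separate samples. In simulated data for the same 20392 genes, with 200 genes changed and 60% of their guides active, the procedure recovered 5.97% of 2-fold, 56.7% of 4-fold and 86.4% of 8-fold changes for CB-103 against DMSO. For DAPT against DMSO these shares were 4.48%, 58.2% and 87.9%, and for CB-103 against DAPT 7.46%, 55.2% and 83.3%. Recovery differed by direction, and of 4-fold changes 76% of the higher and 45.2% of the lower genes were recovered for CB-103 against DMSO, 67.7% and 50% for DAPT against DMSO, and 85.3% and 24.2% for CB-103 against DAPT. Counts of higher and lower genes are therefore not compared with each other. False calls numbered 0 of 99, 5 of 105 and 1 of 98, and 0 of 50 unchanged lists were called in each contrast. The simulated counts were drawn from the fitted model with 1 dispersion per guide for all groups. Between real replicates, chi-square per degree of freedom was 51.1 to 53.9 in DMSO but 12.4 to 15.0 in CB-103. It was computed on raw counts and also rises with depth, which was greater in DMSO. How much of the gap is spread between replicates is therefore not known. With 1 dispersion for all groups, the simulation does not show how unequal spread affects the calls. In pseudo-genes drawn from the non-targeting guides, 5.06%, 3.31% and 2.64% of p-values lay under 0.05 for the 3 contrasts in the same order. For single non-targeting guides in the edgeR test these shares were 5.5%, 8.3% and 4.1%.

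The alternatives fixed before the data were examined were DESeq2 1.42.0 size factors, scaling on non-targeting guides, no count filter and a minimum mean of 50, the DESeq2 Wald test, a normal test in the manner of MAGeCK, a fit of only the 2 groups compared, the replicate number as a block, alpha = 0.25, limma on guide means, fry per gene, each half-library alone, an offset for the general growth trend of each contrast, a pseudocount of 5, medians over guides, a threshold of 0.25, and leaving out each library in turn. The growth-trend offset of a gene is proportional to its mean change from time zero over all endpoint libraries, those compared included. It can therefore remove part of a gene's own effect. Apart from this offset and the permutation test of the essential-gene medians, the time-zero library entered no test between treatments. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.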

Results

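The screen asks which gene losses make T-cell acute lymphoblastic leukaemia cells resistant to Notch inhibition and which make them more sensitive to it. DND-41 is a human line of this leukaemia with activating NOTCH1 mutations. Cells carrying Cas9 and a genome-wide pool of guide RNAs grew until day 21 in DMSO, the solvent, in 5 µM CB-103 or in 10 µM DAPT. CB-103 targets the Notch transcription complex in the nucleus. DAPT inhibits gamma-secretase, the membrane protease that releases the intracellular domain of Notch. A guide that became more abundant marks a gene whose loss went with faster expansion, and a guide that became rarer marks a gene whose loss went with slower expansion or death. The time-zero library held 21930543 counts. The 3 DMSO libraries held 27980083, 25231261 and 20474305, the 3 CB-103 libraries 10016567, 15625535 and 12017992, and the 3 DAPT libraries 14559883, 18011911 and 14571071. The mean of 24.6 ± 3.80 M counts in DMSO (SD, n = 3) was higher than the 12.6 ± 2.84 M in CB-103 and the 15.7 ± 1.99 M in DAPT, with an exact two-sided permutation p of 0.1 for each, the smallest this design allows. Across guides, the pairwise correlation of libraries was 0.592 to 0.624 within DMSO, 0.678 to 0.703 within CB-103 and 0.561 to 0.638 within DAPT. Between groups it was 0.583 to 0.635 for DMSO and CB-103, 0.506 to 0.603 for DMSO and DAPT, and 0.565 to 0.660 for CB-103 and DAPT. The ranges within DMSO and within DAPT thus overlapped those between groups.

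Single guides took more of the DMSO libraries than of the others. The 10 most abundant guides held 0.552% ± 0.0806 of the counts in DMSO (SD, n = 3), 0.162% ± 0.0244 in CB-103 and 0.184% ± 0.0301 in DAPT, with an exact two-sided permutation p of 0.1 for each inhibitor against DMSO. The most abundant guides of the 3 DMSO libraries targeted C5orf22 with 34391 counts, PF4 with 48697 and BCKDHB with 24335, a different gene in each. Guides at 0 counts made up 0.657% ± 0.170 of the library in DMSO, 0.906% ± 0.112 in CB-103 and 1.46% ± 0.517 in DAPT, with 2.00% in DAPT replicate 3. The labels do not say that replicates were separate cultures, so all p-values measure only the spread between these libraries, and the part of that spread that is technical is not known.

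The comparison of DMSO with time zero shows which gene losses were selected over the culture without an inhibitor. Genes of the tRNA-modifying Elongator complex were among those with the highest changes. ELP3, its catalytic subunit, had a log2 change of 2.29 ± 0.57 (SD, n = 3 DMSO libraries against 1 time-zero library), ELP6 2.24 ± 0.19, ELP4 1.85 ± 0.36 and ELP5 1.54 ± 0.25. CTU2, which thiolates the wobble uridine of tRNA, had 1.93 ± 0.42 and DPH3, a diphthamide synthesis protein that also serves Elongator, had 1.48 ± 0.19. The DNA-binding architectural protein CTCF had 1.59 ± 0.11. Among entries with at least 4 tested guides, the lowest change was that of the anti-apoptotic gene BCL2, at -1.98 ± 0.35, and others at the low end were the RNA-binding protein SFPQ at -1.91 ± 0.45, the ribosome rescue factor PELO at -1.91 ± 0.24, the proteasome subunit PSMA6 at -1.83 ± 0.67, the GTPases RHOA at -1.79 ± 0.70 and DNM2 at -1.70 ± 0.43, and the microRNA entry hsa-mir-7641-1 at -1.74 ± 0.21. Among the genes named in advance, CDK6 stood at 1.26 ± 0.20, PIK3R1 at 1.03 ± 0.17 and CDKN1B at -0.78 ± 0.40. With a single time-zero library these changes carry no test.

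Genes that every cell needs were depleted less in DMSO than in either inhibitor. The 179 genes of the proteasome, DNA replication, spliceosome, RNA polymerase II and cytosolic ribosome lists had a median log2 change from time zero of -0.320 ± 0.087 in DMSO (SD, n = 3), -1.003 ± 0.071 in CB-103 and -0.945 ± 0.128 in DAPT. The difference from DMSO was -0.68 for CB-103 and -0.62 for DAPT, with an exact two-sided permutation p of 0.1 in both. The area under the curve separating these genes from 369 olfactory receptor genes, which lymphoid cells do not need, was 0.637 to 0.700 in the DMSO libraries, 0.892 to 0.920 in the CB-103 libraries and 0.819 to 0.868 in the DAPT libraries. Taken over genes after averaging the DMSO libraries, their median change of -0.38 lay below all of 10000 random lists, at percentile 0. In DMSO the 15 pro-apoptotic genes had a median change of 0.47 and the 45 genes of respiratory complex I one of 0.19, both at percentile 100 of their random lists, while the 20 negative regulators of PI3K, AKT and mTOR had -0.28, at percentile 0.68. The mean over DMSO libraries moved to -0.23 with a minimum mean count of 50.

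**Figure D1:**
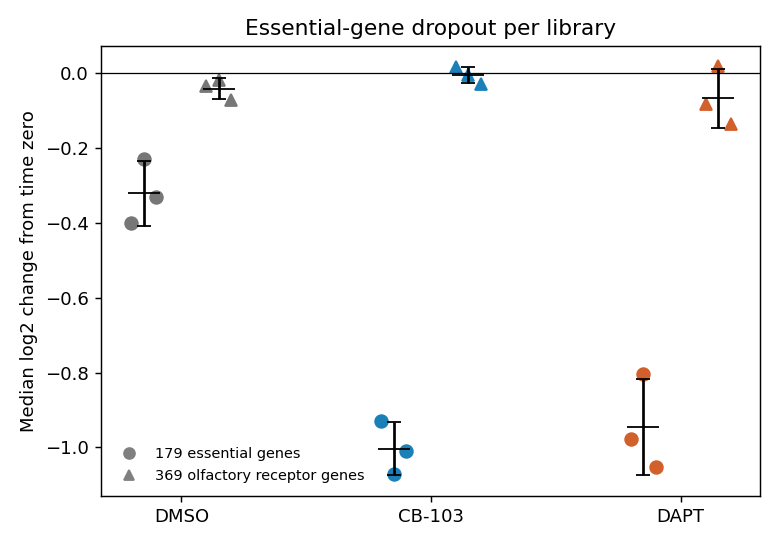
Median log2 change from time zero of 179 essential genes (circles) and 369 olfactory receptor genes (triangles) in each endpoint library, with the mean and SD of each group. Essential genes averaged -0.320 in DMSO, -1.003 in CB-103 and -0.945 in DAPT.

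The comparison of CB-103 with DMSO asks which gene losses protected or sensitised cells under inhibition of the Notch transcription complex. Guides against 2 genes rose. EXTL3, a glycosyltransferase that starts heparan sulfate chains, rose by 0.77 ± 0.29 (log2, SE, n = 3 per group) with a rank-aggregation adjusted p of 8.32e-05 after Benjamini-Hochberg adjustment. PIK3R1, the regulatory subunit that restrains class I PI3 kinase, rose by 0.77 ± 0.30 with a rank-aggregation adjusted p of 0.00111, and for both genes 6 of 6 guides were higher. Guides against 5 genes fell. JAK1, the kinase shared by the IL-7 and other cytokine receptors, had a log2 fold change of -3.30 ± 0.63 with 6 of 6 guides lower and a rank-aggregation adjusted p of 0.00401. Its guides had hardly moved from time zero in DMSO, at -0.09 ± 0.39 (SD, n = 3), and stood at -3.40 ± 0.72 in CB-103. The RNA polymerase III initiation factor BRF1 fell by 2.34 ± 0.47 and PPP4C, the catalytic subunit of protein phosphatase 4, by 1.96 ± 0.31, both with a rank-aggregation adjusted p of 0.0308. The RNA-binding protein MSI2 fell by 1.86 ± 0.49 and RBX1, the RING subunit of cullin ubiquitin ligases, by 1.33 ± 0.35, both with a rank-aggregation adjusted p of 0.0372.

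The next genes in rank under CB-103 did not pass. Upward they were EXT2 at -0.01 ± 0.26 with 3 of 6 guides higher, NDST3 at 0.86 ± 0.29, CARD9 at 1.07 ± 0.45, EXT1 at 0.90 ± 0.26, B4GALT7 at 0.72 ± 0.28, SIRT4, PXDNL, HSP90B1, FAM111B and MTRNR2L4, with rank-aggregation adjusted p from 0.0634 to 0.401. Downward they were DDI2 at -0.77 ± 0.23, the microRNA entries hsa-mir-566 and hsa-mir-8086 with 3 guides each, TRMT112 at -1.67 ± 0.47, RPL35, UXS1 and PSMD3, with rank-aggregation adjusted p from 0.0693 to 0.0849. NOTCH1 had a log2 fold change of -1.18 ± 0.38 with 6 of 6 guides lower and a rank-aggregation adjusted p of 0.471. The gamma-secretase subunit PSENEN had -1.25 ± 0.30, CCND3 -0.92 ± 0.32, MYC -0.59 ± 0.26, CDK6 -0.51 ± 0.25, CDK4 0.73 ± 0.27 and RBPJ, the DNA-binding partner of Notch, 0.55 ± 0.29. MAML1, NCSTN, APH1A, FBXW7, CDKN1B and TLX3, also named in advance, missed the threshold.

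By list, the genes of 5 general essential complexes fell under CB-103 relative to DMSO, where the dropout of these genes was shallower as given above. The 77 cytosolic ribosome genes had a median log2 fold change of -0.74, with a camera adjusted p (limma) of 1.13e-27 and an adjusted p = 0.00551 with an estimated correlation. None of them passed over all genes and 11 passed adjusted over the list alone, among them RPS28 at -2.27 ± 0.52. The 31 proteasome genes had a median of -0.70, camera adjusted p 4.38e-11 and adjusted p = 0.00882 with an estimated correlation, and 4 passed adjusted over the list alone, PSMD3 at -2.17 ± 0.42, PSMC3, PSMB5 and PSMA5. The 28 DNA replication genes had a median of -0.52, camera adjusted p 2.70e-08 and adjusted p = 0.0390 with an estimated correlation, and 3 passed adjusted over the list alone, RRM2 at -2.32 ± 0.50, MCM2 and RPA1. The call was lost for the 24 spliceosome genes, with camera adjusted p 8.29e-06 and adjusted p = 0.0624 with an estimated correlation, and for the 19 RNA polymerase II genes, with 0.00114 and adjusted p = 0.0952 with an estimated correlation. Of the 13 IL-7 receptor, JAK and STAT genes, JAK1 passed over all genes and 3 passed adjusted over the list alone, JAK1, STAT5B at -1.38 ± 0.45 and IL7R at -2.42 ± 0.71, with a camera adjusted p of 0.147 for the list. Of the 14 Notch receptor and transcription complex genes, NOTCH1 and MAML3 at -1.25 ± 0.31 passed adjusted over the list alone, with a camera adjusted p of 0.115.

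In CB-103 against DMSO, edgeR and rank aggregation with Benjamini-Hochberg adjustment called 2 of 20392 genes higher and 5 lower, and 1025 and 1078 lay under an unadjusted p of 0.05. With each of the 6 libraries left out in turn, MSI2 and RBX1 never kept their calls, BRF1 kept its call in 1 case, PPP4C in 2, PIK3R1 in 4, and JAK1 and EXTL3 in 5, with a rank-aggregation adjusted p of 0.0523 for JAK1 without DMSO replicate 2, where none of the 5 lower genes stayed called. With the growth-trend offset the counts were 0 higher and 1 lower, JAK1 keeping its call.

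The comparison of DAPT with DMSO asks the same of gamma-secretase inhibition. Guides against 22 genes rose, led by negative regulators of PI3 kinase and cytokine signalling. PIK3R1 rose by 1.98 ± 0.30 (log2, SE, n = 3 per group) with 6 of 6 guides higher and a rank-aggregation adjusted p of 4.32e-17. SOCS1, a feedback inhibitor of JAK kinases, rose by 2.57 ± 0.27 with a rank-aggregation adjusted p of 1.50e-11. Heparan sulfate enzymes also rose, with EXTL3 at 1.65 ± 0.29 and a rank-aggregation adjusted p of 1.58e-09, EXT1 at 1.56 ± 0.26 and 2.21e-07, B4GALT7 at 1.36 ± 0.28 and 4.63e-04, and EXT2 at 0.67 ± 0.26 and 0.00123. PCGF1, a subunit of a variant Polycomb complex, rose by 2.17 ± 0.34, the T-lineage transcription factor BCL11B by 2.37 ± 0.31, CCNC, the cyclin of the Mediator kinase module, by 1.21 ± 0.24, the CDK6 inhibitor CDKN2C by 1.70 ± 0.30, the telomere-binding protein HMBOX1 by 1.59 ± 0.30 and TM9SF3 by 0.91 ± 0.26, with rank-aggregation adjusted p from 9.95e-09 to 9.36e-04. Guides against PCGF1 were below time zero in DMSO, at -0.63 ± 0.31 (SD, n = 3), and above it in DAPT, at 1.53 ± 0.70. BCL11B averaged -0.58 ± 0.80 in DMSO, with 1 of 3 libraries above time zero, and 1.79 ± 0.28 in DAPT.

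Guides against 60 genes fell under DAPT, among them those of the G1 kinase CDK6 and its partner cyclin. CDK6 fell by 2.45 ± 0.25 with a rank-aggregation adjusted p of 1.36e-05, and CCND3, cyclin D3, had -2.15 ± 0.32 with 4.65e-05. The WD-repeat protein DCAF7 fell by 2.40 ± 0.22 with a rank-aggregation adjusted p of 1.36e-05. PIK3CD, the leukocyte catalytic subunit of PI3 kinase, fell by 2.65 ± 0.33 with a rank-aggregation adjusted p of 1.33e-04. The transcription factor MYC, a direct Notch target in this leukaemia, fell by 2.28 ± 0.26 with 2.03e-04, and NOTCH1 itself by 1.89 ± 0.38 with 0.00183. The Elongator genes ELP3, ELP5 and ELP2 fell by 2.17 ± 0.34, 1.90 ± 0.27 and 1.32 ± 0.31 and DPH3 by 1.24 ± 0.26, with rank-aggregation adjusted p from 1.39e-05 to 0.00148. These Elongator genes and DPH3 had gained in DMSO, and ELP3 stood at 0.11 ± 0.69 from time zero in DAPT (SD, n = 3). The GTPase RAB10 fell by 1.98 ± 0.29, the CDK-binding protein CKS1B by 1.40 ± 0.25 and the membrane protease MME by 1.05 ± 0.23, with rank-aggregation adjusted p from 1.10e-04 to 0.00136. JAK1 fell by 2.87 ± 0.63 with a rank-aggregation adjusted p of 0.00505. Gains in DMSO were not limited to Elongator and DPH3. From time zero, CDK6 stood at 1.26 ± 0.20 in DMSO (SD, n = 3), MME at 1.19 ± 0.11 and DCAF7 at 1.12 ± 0.14. JAK1 at -0.09 ± 0.39 and NOTCH1 at 0.10 ± 0.70 had not clearly gained there. In DAPT, MME stood at 0.14 ± 0.26, CDK6 at -1.19 ± 0.46 and DCAF7 at -1.28 ± 0.09.

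**Figure D2:**
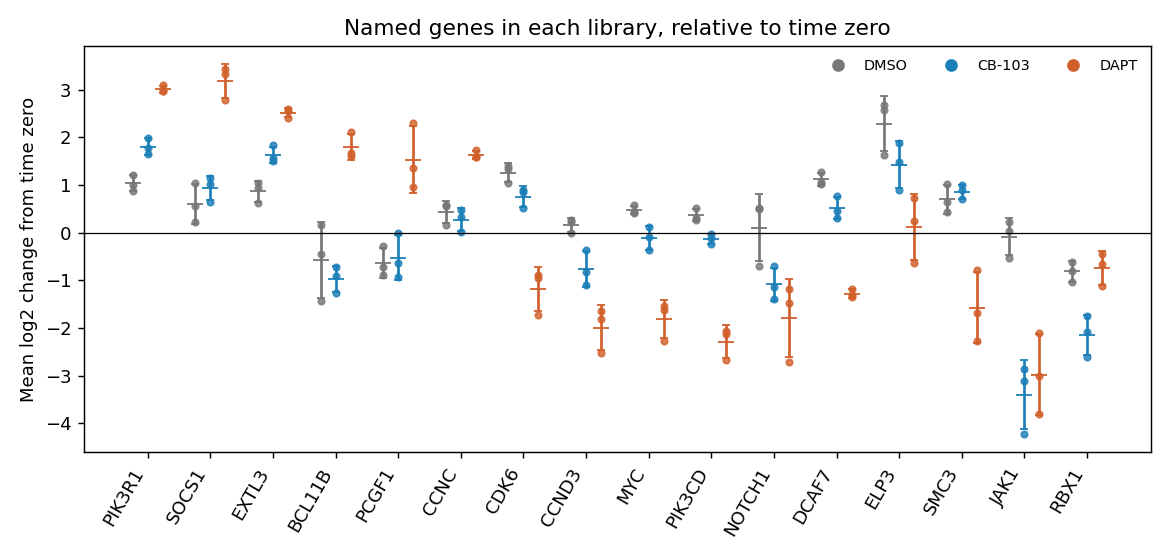
Mean log2 change from time zero over the guides of 16 named genes in each DMSO, CB-103 and DAPT library (points), with the mean and SD of each group of 3. PIK3R1 averaged 1.03 in DMSO, 1.80 in CB-103 and 3.01 in DAPT, and JAK1 -0.09, -3.40 and -2.97.

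By list, the 20 negative regulators of PI3K, AKT and mTOR rose under DAPT, with a median of 0.31, 14 members above 0, a camera adjusted p of 0.00456 and an adjusted p = 0.0935 with an estimated correlation. Of its members PIK3R1 passed, over all genes and adjusted over the list alone, and the list had the low change in DMSO given above. The 14 cytokine signalling inhibitors rose with a median of 0.07, camera adjusted p 0.0394 and adjusted p = 0.134 with an estimated correlation. SOCS1 passed over all genes, and 2 members passed adjusted over the list alone, SOCS1 and the phosphatase PTPN2 at 0.94 ± 0.24. The 15 G1 inhibitors rose with a median of 0.10, camera adjusted p 0.0444 and adjusted p = 0.284 with an estimated correlation, and CDKN2C passed over all genes. In this list 8 members lay above 0, and it missed the threshold with fry, at a fry adjusted p of 0.186. Among 23 positive members of PI3K, AKT and mTOR signalling, 3 fell over all genes and adjusted over the list alone, PIK3CD, RPTOR at -1.73 ± 0.24 and MTOR at -1.71 ± 0.26, with a camera adjusted p of 0.226 for the list. Among 15 G1 cyclins, kinases and E2F genes, CDK6, CCND3 and CKS1B fell, 3 by either count, with a camera adjusted p of 0.0524.

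The 13 gamma-secretase and Notch maturation genes fell under DAPT, with a median of -0.26, camera adjusted p 0.0159 and adjusted p = 0.102 with an estimated correlation. NCSTN, the substrate-binding subunit, had -1.30 ± 0.29 with a rank-aggregation adjusted p of 0.0889 and passed adjusted over the list alone. The subunits PSENEN and APH1A had -0.95 ± 0.30 and -0.91 ± 0.25 and did not pass. Of 14 Notch receptor and transcription complex genes, NOTCH1 fell over all genes and 3 passed adjusted over the list alone, NOTCH1, MAML3 at -1.01 ± 0.31 and MAML1 at -1.41 ± 0.32, with a camera adjusted p of 0.700. RBPJ had 0.18 ± 0.29 and FBXW7, the ligase that degrades active Notch, 0.37 ± 0.36. The 15 pro-apoptotic genes fell, with a median of -0.63, camera adjusted p 0.001002 and adjusted p = 0.0571 with an estimated correlation. In that list CYCS, which also carries electrons in the respiratory chain, fell by 1.36 ± 0.39, while CASP8, the initiator caspase of death receptors, rose by 1.14 ± 0.23, and BAX, APAF1 and FADD passed with CYCS adjusted over the list alone. The 45 complex I genes fell with a median of -0.26, camera adjusted p 0.0399 and adjusted p = 0.134 with an estimated correlation. Both of these lists had gained in DMSO relative to random lists, as given above.

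Essential complexes also fell under DAPT. Medians were -0.91 for the 19 RNA polymerase II genes, -0.78 for 24 spliceosome genes, -0.68 for 28 DNA replication genes, -0.53 for 77 cytosolic ribosome genes and -0.52 for 31 proteasome genes, with camera adjusted p of 8.40e-08, 1.11e-09, 1.15e-04, 6.64e-07 and 0.001002 in that order. Their adjusted p = 0.0390, 0.0390, 0.0571, 0.0390 and 0.0495 with an estimated correlation, so the DNA replication call was lost. RPL15 at -1.98 ± 0.41 was the member that passed over all genes. Among 20 leukaemia transcription factors BCL11B rose and MYB, a T-lineage regulator, fell by 1.76 ± 0.41, with a camera adjusted p of 0.710, and BCL11B, IKZF1 and ETV6 higher and MYB lower, 3 and 1, passed adjusted over the list alone. Among 17 chromatin tumour suppressors the demethylase KDM6A rose by 0.98 ± 0.22 and CTCF fell by 1.28 ± 0.28, with a camera adjusted p of 0.512. CDKN1B had 0.96 ± 0.36, CDK4 0.40 ± 0.27 and TLX3, the transcription factor activated in DND-41, -0.70 ± 0.28, and none of these passed.

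In DAPT against DMSO, edgeR and rank aggregation with Benjamini-Hochberg adjustment called 22 of 20392 genes higher and 60 lower. The lower count was 20 without DMSO replicate 1, 24 without DMSO replicate 2 and 36 without DAPT replicate 2, the higher count was 10 without DAPT replicate 1, and the calls of CASP8 and MYB were lost whichever library was left out, those of KDM6A and RPL15 in 5 of 6 cases, CDKN2C and CYCS in 4, MTOR and RAB10 in 3, and JAK1 in 2. With the growth-trend offset the counts were 9 higher and 58 lower and B4GALT7, EXT2, TM9SF3, KDM6A, CASP8, RPL15 and MYB lost their calls, and EXT2 and CKS1B changed sign in half-library B alone, at -0.31 and 0.16.

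**Figure D3:**
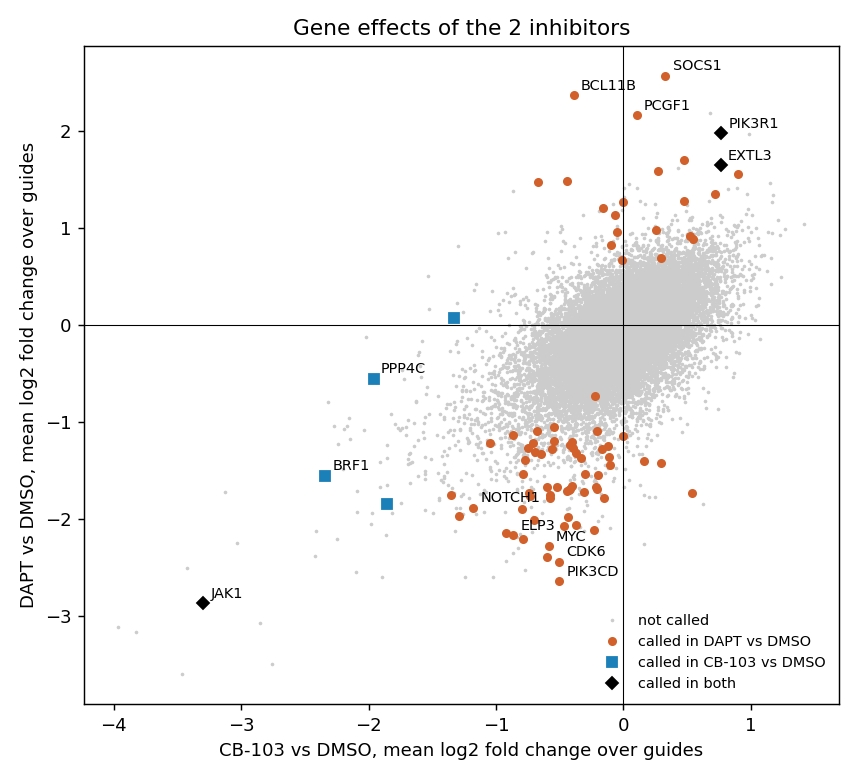
Mean log2 fold change over guides of each gene under CB-103 (horizontal) and DAPT (vertical), each against DMSO, for 20392 genes, with genes called in DAPT (orange circles), in CB-103 (blue squares) or in both (black diamonds). JAK1 lies at -3.30 and -2.87, and PIK3R1 at 0.77 and 1.98.

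The direct comparison of CB-103 with DAPT asks where the inhibitors differed, at doses that were not the same, 5 µM and 10 µM. Guides against 61 genes were higher in CB-103. SMC3, a core subunit of cohesin, was higher by 2.43 ± 0.35 (log2, SE, n = 3 per group) and DCAF7 by 1.79 ± 0.22, both with a rank-aggregation adjusted p of 3.83e-07. CDK6 was higher by 1.94 ± 0.25 with a rank-aggregation adjusted p of 4.59e-06, PIK3CD by 2.14 ± 0.33 with 4.85e-06, CKS1B by 1.57 ± 0.25 with 8.55e-05 and the condensin subunit SMC4 by 2.27 ± 0.46 with 1.44e-04. CCND3 at 1.23 ± 0.32 and MYC at 1.70 ± 0.26 were also called, with rank-aggregation adjusted p of 7.38e-04 and 0.00148. Guides against 52 genes were lower in CB-103. SOCS1 had -2.24 ± 0.27 with a rank-aggregation adjusted p of 3.52e-11, PIK3R1 -1.21 ± 0.30 with 1.25e-09, DPY30, a subunit of histone H3 methyltransferase complexes, -2.15 ± 0.25 with 6.80e-09, PCGF1 -2.06 ± 0.34 with 6.88e-09, BCL11B -2.76 ± 0.31 with 2.67e-08 and CCNC -1.36 ± 0.24 with 1.84e-07.

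The 20 negative regulators of PI3K, AKT and mTOR were lower in CB-103 than in DAPT, with a median of -0.17, a camera adjusted p of 4.56e-06 and an adjusted p = 0.0390 with an estimated correlation. Over all genes 4 passed, PIK3R1, TSC1 at -1.89 ± 0.30 and TSC2 at -1.60 ± 0.31, which restrain mTOR together, and NPRL3 at -1.02 ± 0.35, and 6 passed adjusted over the list alone. From time zero, TSC1 stood at -0.67 ± 0.41 in DMSO (SD, n = 3), -1.60 ± 0.20 in CB-103 and 0.28 ± 0.19 in DAPT. Of the 23 positive members, PIK3CD, RPTOR at 1.42 ± 0.24 and MTOR at 1.28 ± 0.26 were higher and RRAGA, a GTPase that recruits mTOR to lysosomes, was lower at -1.44 ± 0.32, with a camera adjusted p of 0.307 for the list. Adjusted over the list alone, 3 members were higher and 3 lower. The 14 cytokine signalling inhibitors were lower in CB-103, with a median of -0.20, camera adjusted p 0.00646 and adjusted p = 0.0935 with an estimated correlation, and SOCS1 passed over all genes. The 12 genes of the Polycomb list were lower, with camera adjusted p 0.0118 and adjusted p = 0.0952 with an estimated correlation, and PCGF1 alone passed. The 13 gamma-secretase and maturation genes were higher in CB-103, with a median of 0.37, 12 members above 0, camera adjusted p 0.00526 and adjusted p = 0.0922 with an estimated correlation. APH1A, a gamma-secretase subunit, passed over all genes at 1.18 ± 0.25, and 2 members passed adjusted over the list alone. The 15 pro-apoptotic genes were higher, with a median of 0.38, camera adjusted p 0.00889 and adjusted p = 0.0935 with an estimated correlation. CYCS at 1.25 ± 0.39 and BAX at 0.81 ± 0.23 were higher and CASP8 was lower at -1.21 ± 0.23 over all genes, and 7 were higher adjusted over the list alone.

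The 77 cytosolic ribosome genes were lower in CB-103 than in DAPT, with a median of -0.27, a camera adjusted p of 4.83e-06 and an adjusted p = 0.0495 with an estimated correlation, with RPS21 at -1.28 ± 0.32 passing over all genes. The proteasome list was lower with camera adjusted p 0.0169 and adjusted p = 0.0935 with an estimated correlation. The spliceosome and RNA polymerase II lists were higher, with medians of 0.36 and 0.28, camera adjusted p of 0.00624 and 0.00499, and adjusted p = 0.153 and 0.132 with an estimated correlation. Complex I genes were higher with a median of 0.19, camera adjusted p 0.0394 and adjusted p = 0.134 with an estimated correlation. Other list members called were the adaptor GRB2 at -1.07 ± 0.28, the T-lineage factor GATA3 at -0.78 ± 0.27, CDKN2C at -1.22 ± 0.30, the demethylase KDM5A at 1.18 ± 0.26 and MAX, the partner of MYC, at -0.23 ± 0.26 with 2 of 6 guides lower. NOTCH1 differed by 0.71 ± 0.38 with a rank-aggregation adjusted p of 0.910, and its values against DMSO were -1.18 ± 0.38 in CB-103 and -1.89 ± 0.38 in DAPT. A threshold missed in this way does not show that the inhibitors acted alike.

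In CB-103 against DAPT, edgeR and rank aggregation with Benjamini-Hochberg adjustment called 61 of 20392 entries higher and 52 lower, including 2 microRNA entries. The counts were 26 higher and 27 lower without DAPT replicate 1, 32 and 27 without DAPT replicate 2, and 33 lower without CB-103 replicate 2. CCND3 changed sign in half-library B alone, at -0.04, MAX changed sign in half-library A alone, at 0.07, and the call of RPS21 was lost whichever library was left out, those of MAX and BAX in 5 of 6 cases, TSC2 and GATA3 in 4, NPRL3, CDKN2C and KDM5A in 3, and MYC and MTOR in 2.

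Across the 3 contrasts camera put 26 of 96 list tests past the threshold, and 9 stayed past it with an estimated correlation. The chromatin tumour suppressors reached a camera adjusted p of 0.0524 under CB-103. The lists of Notch turnover, IL-7 receptor and JAK, RAS and MAPK members, RAS and MAPK inhibitors, leukaemia transcription factors, the MYC network, T-cell receptor signalling, p53, anti-apoptotic genes, NF-kB inhibitors, the Mediator kinase and tail, drug efflux, hormone receptors, AMPK and glucose or glutamine metabolism, the mitochondrial ribosome and olfactory receptors passed in no contrast, with camera adjusted p from 0.0839 to 0.966.

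The called genes of the inhibitors overlapped in EXTL3 and PIK3R1 upward and in JAK1 downward. Upward, 2 genes were shared where lists of 2 and 22 genes drawn independently would share 0.00216, and downward 1 was shared where lists of 5 and 60 would share 0.0147. Across genes, which are not independent replicates, the log2 fold changes of CB-103 and DAPT against DMSO correlated with Pearson's r = 0.592 and Spearman's rho = 0.557. Both comparisons use the same 3 DMSO libraries. In 20 simulations all 9 endpoint libraries, DMSO included, were redrawn without a change between groups, and r ran from 0.518 to 0.539. Guides were drawn independently of each other, so deviations that the guides of a gene share in the real DMSO libraries are absent from the simulations. The covariance was 0.0983 against 0.0503 in the simulations, a difference of 0.0480. Dividing 3 DMSO libraries would leave a single control on one side and was not done, so part of the excess overlap may come from the shared controls.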

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

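Most alternatives were chosen before the data were examined, and the 2 chosen after the data had been seen, leaving out guides that had expanded in a single library and thinning all libraries to one total, are named as such below.

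For CB-103 against DMSO, the 2 higher genes became 5 with a minimum mean count of 50, 1 with a fit of only the 2 groups compared, 1 in half-library B, and 7 at a threshold of 0.25. They became 0 with the MAGeCK-style normal test, 0 with limma on guide means, 0 with fry per gene and 0 with the growth-trend offset. The 5 lower genes became 1 with limma on guide means, 0 with fry per gene, 0 in half-library A, 0 in half-library B, 1 with the growth-trend offset and 31 at a threshold of 0.25. A half-library has fewer guides per gene and so less power, and for the other settings the cause was not tested. Leaving out 1 library gave 1 to 6 higher and 1 to 3 lower genes. The higher count was 1 without DMSO replicate 3 and 6 without CB-103 replicate 3. The lower count was 1 without DMSO replicate 1, DMSO replicate 2 or CB-103 replicate 1, 2 without CB-103 replicate 2 or 3, and 3 without DMSO replicate 3.

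For DAPT against DMSO, the 22 higher genes became 12 with the MAGeCK-style normal test, 44 with limma on guide means, 12 with fry per gene, 7 in half-library A, 8 in half-library B, 9 with the growth-trend offset and 35 at a threshold of 0.25. Leaving out 1 library gave 10 to 19, with 10 without DAPT replicate 1 and 19 without DMSO replicate 2. The 60 lower genes became 26 with the MAGeCK-style normal test, 228 with limma on guide means, 33 with fry per gene, 9 in half-library A, 8 in half-library B and 120 at a threshold of 0.25. Leaving out 1 library gave 20 to 52, with 20 without DMSO replicate 1, 24 without DMSO replicate 2 and 36 without DAPT replicate 2. In half-library B, EXT2 turned from 0.67 to -0.31 and CKS1B from -1.40 to 0.16.

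For CB-103 against DAPT, the 61 genes higher in CB-103 became 39 with the MAGeCK-style normal test, 7 with fry per gene, 16 in half-library A, 9 in half-library B and 117 at a threshold of 0.25. Leaving out 1 library gave 26 to 63, with 26 without DAPT replicate 1 and 32 without DAPT replicate 2. The 52 genes lower in CB-103 became 7 with fry per gene, 18 in half-library A, 17 in half-library B and 86 at a threshold of 0.25. Leaving out 1 library gave 27 to 43, with 27 without DAPT replicate 1 or 2 and 33 without CB-103 replicate 2. CCND3 turned from 1.23 to -0.0445 in half-library B and MAX from -0.23 to 0.0683 in half-library A.

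The 26 list tests past the threshold became 9 with an estimated correlation between genes, and ran from 19 to 29 with 1 library left out. The correlation of 0.592 between the effects of the inhibitors ran from 0.535 without DAPT replicate 2 to 0.662 without DMSO replicate 1, and was 0.539 without DAPT replicate 1. The essential-gene dropout in DMSO, -0.32, became -0.23 with a minimum mean count of 50 and ran from -0.36 to -0.28 with 1 library left out. Its difference from DMSO ran from -0.72 to -0.64 for CB-103 and from -0.70 to -0.57 for DAPT with 1 library left out, and for DAPT it was -0.51 with the median over guides.

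With the replicate number as a block, the counts were 2 higher and 4 lower for CB-103, 26 and 64 for DAPT, and 68 and 48 for CB-103 against DAPT. The labels do not say that equal replicate numbers were paired. Deviations of libraries with the same number correlated from -0.00737 to 0.00626 in 9 pairs, and those with different numbers from -0.00565 to 0.00861 in 18 pairs.

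Leaving out the guides that had expanded in a single library, chosen after seeing the data, gave 2 higher and 5 lower for CB-103, 20 and 58 for DAPT, and 61 and 50 for the direct comparison. Thinning all libraries to one total, also chosen after seeing the data, gave 3 and 4, 20 and 50, and 57 and 44.

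Of 3425 values for named genes under the other settings, 3166 stayed the same, 214 were weaker, 41 stronger and 4 reversed, and of 1470 with 1 library left out, 1354 stayed the same, 104 were weaker and 12 stronger. These values cover 245 results, those not called in the main analysis included. An uncalled gene that stayed uncalled counts as the same and could not become weaker. The totals therefore do not give the share of calls kept, which was lower. For the lists that passed, 21 of 130 values under other settings and 18 of 234 with 1 library left out were weaker, and the rest stayed the same.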

Other observations

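The gene groups in this part were put together after the effects of single genes had been seen, and the tests of general selection on heparan sulfate genes and of Elongator were also chosen after the result was seen. The tests of depth, expanded guides and selection in DMSO, and that of the remaining heparan sulfate genes, were written before their values were computed.

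Cohesin and condensin, the ring complexes that organise chromosomes, had guides higher in CB-103 than in DAPT. Their 13 genes had a median log2 fold change of 1.24, with a camera p of 1.27e-15 (0.00193 with an estimated correlation), and 6 were called, among them SMC3 at 2.43 and SMC4 at 2.27. Against DMSO the group fell under DAPT, with a median of -1.54, a camera p of 1.47e-11 (0.00445 with an estimated correlation) and 4 called, and under CB-103 its median was 0.13 with a camera p of 0.944. Neddylation genes, which attach NEDD8 to cullin ligases, were lower in CB-103 than in DAPT, with a median of -1.43 over 8 genes, a camera p of 1.90e-14 (2.18e-04 with an estimated correlation) and 5 called, NEDD8 at -2.04, NAE1 at -1.93, UBA3 at -1.93, UBE2M at -1.46 and RBX1 at -1.40. Against DMSO the neddylation medians had opposite signs, -0.65 under CB-103 and 0.57 under DAPT, with 1 gene called in each. Above 0 lay 1 of the 8 genes under CB-103 and 6 under DAPT. Not every gene changed direction, since RNF7 and UBE2F were lower and DCUN1D1 higher under both inhibitors. The GATOR2 complex, which activates mTORC1 in response to amino acids, fell under DAPT against DMSO, with a median of -1.45 over 5 genes, a camera p of 3.38e-08 (0.00778 with an estimated correlation) and 4 called, and was higher in CB-103 than in DAPT with a median of 1.31. GATOR1 and KICSTOR, which oppose it, had a median of 0.49 over 7 genes in DAPT against DMSO, with a camera p of 0.00539 and none called, and the adjusted p rose from 0.00809 to 0.0555 with an estimated correlation. COMPASS genes, to which DPY30 belongs, were lower in CB-103 than in DAPT, with a median of -0.79 over 10 genes, a camera p of 3.04e-11 (0.00280 with an estimated correlation) and 3 called. Their median against DMSO was -0.50 under CB-103 and 0.43 under DAPT. Because the groups were gathered around genes already seen to change, these p-values overstate the evidence.

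The library lists TMEM48 with 4 guides and NDC1 with 6 guides as separate entries, and both are names of the nuclear pore gene NDC1. Both entries were called higher in CB-103 than in DAPT, TMEM48 at 1.92 ± 0.33 with a rank-aggregation adjusted p of 0.0285 and NDC1 at 1.35 ± 0.26 with a rank-aggregation adjusted p of 0.0369.

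Essential genes dropped out more in both inhibitors than in DMSO. The difference in depth argues little for it, since with all libraries thinned to one total the smaller of the 2 differences was -0.588, and leaving out expanded guides gave -0.592 (SD 0.121). For less selection overall in DMSO, the 100 genes highest in 1 DMSO library changed by 0.67 in the other DMSO libraries, 0.118 (SD 0.0680) above the higher inhibitor group, while the 100 lowest changed by -0.71 there against -1.04 in CB-103 and -1.10 in DAPT. The prediction written beforehand used the highest genes alone, and by it this excess, larger than its SD, would have counted against less selection in DMSO. Choosing genes in a DMSO library favours the other DMSO libraries, which that prediction did not allow for, so the gains exclude nothing. The lowest genes were chosen for deep dropout, so their shallower losses in DMSO repeat the pattern itself. They do not separately favour weaker selection. Weaker selection in general, outgrowth of unedited cells, a greater dependence on these genes under either inhibitor and different handling of the DMSO cultures could each give this pattern and stay open.

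Heparan sulfate assembly genes rose in DAPT against DMSO, with a median of 1.32 (SD 0.384) over 6 called genes. Gains of this group were not limited to DAPT. From time zero its median was 0.72 in DMSO, 1.15 in CB-103 and 1.81 in DAPT, with NDST2 at -0.18 in DMSO. In CB-103 against DMSO the median was 0.63, with 5 of 6 genes above 0 and 1 called. If loss of the chain itself gave the advantage, the remaining 14 assembly genes might rise as well. These 14 were the ones not called in this same contrast, so the clearest risers had been taken out beforehand. Their camera p was 0.0452 upward, 0.0621 after adjustment and 0.207 with an estimated correlation, with a median of 0.13. That choice of genes favoured a weak result, so the test cannot decide the question. With the growth-trend offset the 6 genes had a median of 0.947 (SD 0.299) and 2 stayed called, while NDST2 lost its call at nearly the same fold (0.89 and 0.82), and why was not tested. The offset is computed in part from the DAPT libraries, so it takes away some of these genes' own effect. The smaller median and the lost calls therefore do not show a general difference in selection. Whether part of the pattern comes from such a difference stays open.

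Elongator genes were lower in DAPT than in DMSO, with a median of -1.55 over 6 genes and 5 called. From time zero their median was 1.90 in DMSO and 0.292 in DAPT (SD 0.537), so the contrast may reflect a gain in DMSO that is absent under DAPT and not a loss under DAPT. In CB-103 the median from time zero was 1.46. Against DMSO it was -0.55 under CB-103 with none called, and 5 of the 6 were called higher in CB-103 than in DAPT. The other genes of wobble uridine modification were also lower, with a camera p of 2.95e-08 and 4 of 5 called, but they were put together after their effects had been seen, so this does not favour loss of the tRNA modification over another role of Elongator. Why its loss favoured growth in DMSO but less so in DAPT stays open.

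The libraries of each contrast were regrouped in all 10 possible ways of 3 against 3. For CB-103 against DMSO, 1 of the 10 splits, the real one, had as many higher genes, lower genes or lists, with real values of 2, 5 and 5 and highest other values of 0, 0 and 2. For DAPT against DMSO it was again 1 of the 10 splits, with 22, 60 and 13 against 0, 0 and 3. For CB-103 against DAPT it was 1 of the 10 splits, with 61, 52 and 10 against 0, 0 and 1. The lists of each split were adjusted within that split alone, not over the contrasts together as in the list tests above. The count of 13 for DAPT against DMSO is therefore higher than the number of lists that passed there. Adjusted over the contrasts together, the Polycomb list and the G1 cyclins, kinases and E2F list missed the threshold, each at a camera adjusted p of 0.0524. With 10 splits no share under 0.05 is possible.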
